A study of Escherichia coli with 4 samples.

How the data were processed

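Total RNA from the wild-type strain W3110 and its luxS mutant (2 arrays each) was extracted with a Qiagen RNeasy kit, per the labels' protocols, after growth in LB medium with 0.8% glucose at 30 °C, shaken at 250 rpm in 50 ml flasks, to an optical density of 1.0. Fragmented cDNA was labelled at its 3′ ends with biotin-ddUTP, per the labels' protocols, and hybridised to the Affymetrix E. coli antisense genome array. The deposited values are signal intensity values on a linear scale, made with MAS5 version 5.1, per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set into a signal that is never negative, and low signals vary widely on the log scale. The deposited intensity values had the same mean, 500.2, on each array when 2% of the values at each end were left out, so each array had been scaled to a common level before deposit. Such a scaling is 1 factor per array and leaves differences that follow signal level in place. Scanner files and detection calls were not used here.

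The table held 7312 probe sets. Of these, 4345 carried the b-number of a gene, 2886 lay between genes, 59 were for vectors and phages and 22 were spike controls. Names were updated by b-number through a RefSeq gene table of E. coli K-12 MG1655 (assembly ASM584v2), used only for names and neighbours. By locus tag 4183 gene probe sets matched, 113 matched by a former locus tag, and 49 kept the array's own name. They stood for 4285 distinct genes, and 54 genes had more than 1 probe set. The platform annotation listed 4398 probe sets, 3804 with 1 symbol and 594 with several, and did not list 2914. It was used only for the assignment of an intergenic probe set. Suffixes mark 126 gene probe sets as shared between transcripts or families, and their signals may mix several transcripts.

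Values were analysed as log2 of the deposited signal, with no offset and no further normalization, since no value was 0 or below. Gene probe sets whose mean log2 signal over the 4 arrays lay in the lowest 25% were left out, below a signal of 73.4. The probe set with the highest mean was taken for each gene, which left 3241 genes. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior gave 14.7 total degrees of freedom. Intergenic probe sets were filtered within their class, below a signal of 18.5, and fitted apart. Vector, phage and spike probe sets carry no b-number and were kept out of the gene test. With 2 arrays per strain there are 3 splits of the arrays, and the smallest two-sided p of an exact permutation test is 0.333, so calls rest on the spread shared over genes. Where several probe sets of a gene passed the filter (17 genes), 14 genes had the same sign in all of them.

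Gene lists (32, with 745 entries, 742 of which had a probe set) were fixed before the data were examined, as were the design, the main set of alternatives and the rule for named genes. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares the members with the other genes, and fry asks whether they move on balance one way. The rule named luxS, up to 12 genes per direction with the largest difference without overlap, called genes first, 4 members of each called list and up to 2 of every other list by moderated t, and every tested member of the lists for AI-2 synthesis, the lsr operon and the neighbourhood of luxS. Where fewer than 12 genes were called, the places were filled with genes that had not passed the test. It also named called intergenic probe sets, of which there were 0. The former gene models, metU and the second cyuA probe set appear beside the genes they adjoin.

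The procedure was tested on 20 simulated data sets of 3241 genes with 200 changed genes. It recovered 78.5% of the genes changed 2-fold and 99.3% of those changed 4-fold, with 3.94% false among the called and 0 wrong signs. The simulated spread was drawn from the variance trend that the test assumes. With 200 changed genes the adjustment is also less strict than with the 3 genes called here, so these shares may not hold for the real data. A list whose members varied together without a group effect was tested alone, without adjustment over lists. Its camera p was under 0.05 in 14 of 20 data sets with the preset correlation and in 2 of 20 with the estimated one. Only the ribosomal protein list was simulated so, with a chosen shared SD of 0.15 log2 per array. These counts need not hold for other lists or for the calls below, which use p adjusted over all lists.

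The alternatives fixed in advance were median centring, quantile normalization, an offset of 37.2 before log2, no filter, the lowest 50% left out, no intensity trend, a robust trend, the replicate number as a block, each array left out in turn, and the other gene set tests. Fits that left out an array assume that the lone array of its strain varies like the other strain's arrays. Further alternatives chosen after seeing the data kept all probe sets of a gene, left out shared designs, kept the vector and phage probe sets, left out rRNA and tRNA genes, or left luxS out of the AI-2 list. Tables were handled with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.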

Results

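Transcript levels were compared between the Escherichia coli K-12 strain W3110 and a luxS mutant of it. LuxS is the enzyme that releases homocysteine and the precursor of autoinducer 2 (AI-2), a signal molecule of bacterial quorum sensing, from S-ribosylhomocysteine. Both strains were grown in LB medium with 0.8% glucose at 30 °C to an optical density of 1.0. Total RNA was hybridised as labelled cDNA to an antisense genome array with probe sets for annotated genes and for the stretches between them. There were 2 arrays per strain, 4 in all, and this number limits the precision of every value. The labels do not say that the arrays of a strain came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The median signal of the gene probe sets lay between 221 and 231 (MAS5 signal units) on the 4 arrays. Arrays of one strain were no closer to each other than arrays of different strains. The median absolute log2 difference was 0.226 between the mutant arrays and 0.240 between the wild-type arrays, against 0.211 to 0.277 between arrays of different strains.

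The comparison asked which transcripts depend on luxS during growth with glucose. Of 3241 genes tested with limma, 3 differed between the strains at an adjusted p under 0.05. Signals of luxS itself and of metT, a gene for elongator methionine tRNA, fell in the mutant, and those of cyuA, which encodes a cysteine desulfidase, rose. Most other genes lay close to the wild type, with 94.5% of the tested genes within 0.5 of 0 on the log2 scale and a median difference of 0.005. At an unadjusted p under 0.05, 238 genes differed, 140 higher and 98 lower, where 162 would be expected by chance. The mutant and wild-type signals did not overlap for 37.5% of the genes, and chance gives 33.3% for 2 arrays against 2. Among these, 7 genes were at least 2-fold apart, 3 higher and 4 lower in the mutant. With 1 array against 2, chance leaves 66.7% without overlap, so the counts with an array left out (36 and 12 without mutant replicates 1 and 2, 12 and 32 without wild-type replicates 1 and 2) cannot be compared with 7. After centring each array on its median, metT lost its call and the calls were 1 higher and 1 lower. No gene was called without an intensity trend in the variance or with a robust one. Leaving out 1 array gave 30 genes without mutant replicate 1, 13 without mutant replicate 2, 8 without wild-type replicate 1 and 56 without wild-type replicate 2. All 3 genes were among those called each time.

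**Figure D1:**
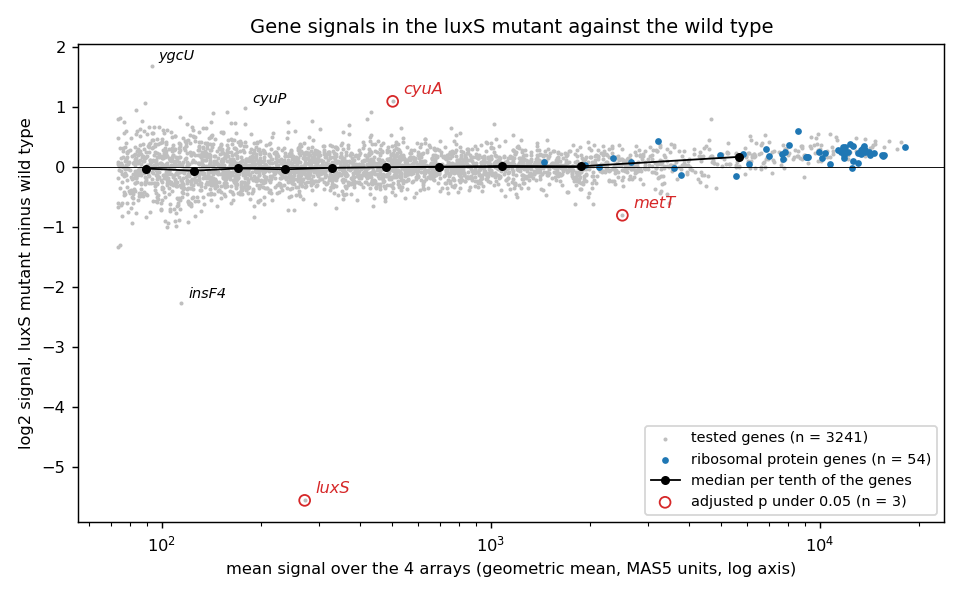
Each point is 1 of the 3241 tested genes, placed by its mean signal over the 4 arrays (MAS5 signal units, log axis) and its log2 difference, luxS mutant minus wild type. Red circles mark the 3 genes with an adjusted p under 0.05, blue points the 54 ribosomal protein genes, and the black line joins the medians of 10 equal classes of signal level, which reached 0.17 in the brightest class.

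The luxS probe set (ygaG in the array's naming, b2687) checked the labels. Its signal was 17.4 and 89.8 on the mutant arrays (mean 53.6 ± 51.2, SD, n = 2) and 1680 and 2084 on the wild-type arrays (1882 ± 286, SD, n = 2). The log2 difference of the measured signals was −5.57 (SE 0.48, limma adjusted p = 2.87e-05). Both mutant signals lay within the range of the array's 59 vector and phage probe sets, whose 95th percentile was 117 on mutant replicate 1 and 182 on mutant replicate 2. The fold therefore has only a lower bound. The lower wild-type signal was 9.22-fold above the higher of these percentiles, so the luxS signal was at least 9.22-fold lower in the mutant. The sources used here do not say which part of luxS was disrupted or where the probes lie against it. The call was lost without an intensity trend (adjusted p = 0.201) and with a robust trend (adjusted p = 0.572), while the other 14 alternatives kept it. Adjusted p over all 16 alternatives ranged from 2.09e-141, in a fit that left out an array, to 0.572.

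The cyuA gene rose in the mutant together with a neighbouring probe set of the same gene. Its signal (yhaM, b3108) was 739 ± 105 (SD, n = 2) in the mutant and 345 ± 21.8 (SD, n = 2) in the wild type, a log2 difference of 1.09 (SE 0.17, limma adjusted p = 0.0225). A second probe set, designed for yhaN (b3109), which the current annotation merges into cyuA, gave 712 ± 30.6 (SD, n = 2) against 250 ± 27.5 (SD, n = 2), a log2 difference of 1.52 with an adjusted p of 6.09e-04 when all probe sets were kept. The adjacent gene cyuP (yhaO, b3110), which encodes a cysteine uptake protein, measured 252 ± 2.11 (SD, n = 2) against 128 ± 3.80 (SD, n = 2). Its log2 difference of 0.98 (SE 0.23) did not pass the test (adjusted p = 0.293). The cyuA call was lost without a filter on low signals (adjusted p = 0.143), without an intensity trend (0.488) and with a robust trend (0.0502). It held in the other 13 of 16 alternatives, and adjusted p ranged from 3.36e-05 to 0.488.

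The metT probe set (b0673) fell from 3332 ± 388 (SD, n = 2) in the wild type to 1899 ± 122 (SD, n = 2) in the mutant, a log2 difference of −0.81 (SE 0.14, limma adjusted p = 0.0400). Its design is shared with other transcripts, so its signal can include other transcripts. How much tRNA the RNA preparations kept was not measured here. The probe set of metU, which encodes the same tRNA species, gave 1455 ± 24.4 (SD, n = 2) against 2232 ± 223 (SD, n = 2) and a log2 difference of −0.61 (adjusted p = 0.215 with all probe sets kept). The metT call was lost after median centring (adjusted p = 0.125), without a filter (0.207), without an intensity trend (0.767) and with a robust trend (0.0502). It held in the other 10 of 14 alternatives that kept the probe set, and adjusted p ranged from 3.36e-05 to 0.767.

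**Figure D2:**
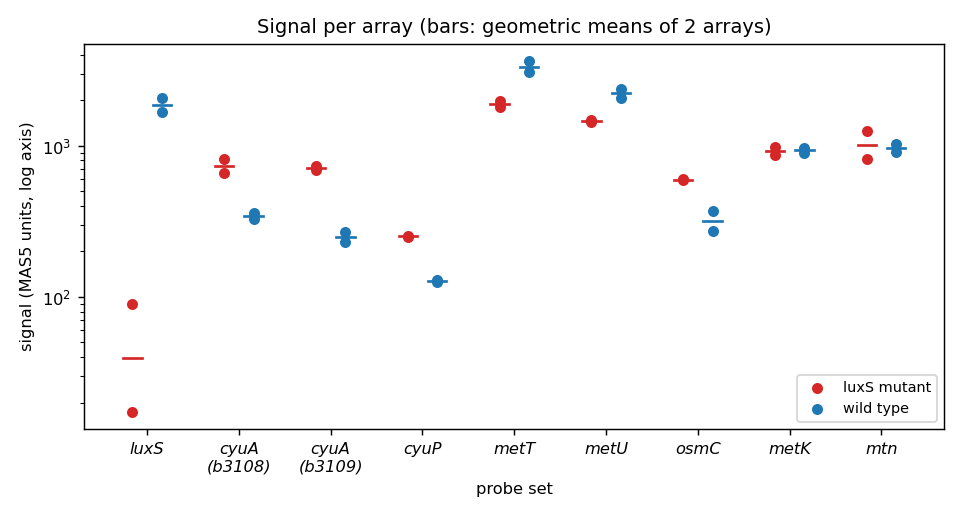
Each dot is the signal of 1 array (MAS5 signal units, log axis) for a probe set, in red for the luxS mutant and in blue for the wild type, and each bar is the geometric mean of 2 arrays. The mutant dots lie apart from the wild-type dots for luxS, both cyuA probe sets, cyuP, metT, metU and osmC. For metK and mtn the wild-type dots lie between the mutant dots.

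The genes that follow had the largest differences without overlap between the strains, and none of them passed the test. The higher signals in the mutant included ygcU (log2 difference 1.69, adjusted p = 0.300), the protamine-like tpr (1.07), yjfK (0.95) and ascF (0.92), a component of a sugar phosphotransferase system. They also included osmC (0.92, adjusted p = 0.156), a peroxidase of osmotic and stationary-phase stress, raiA (0.80, adjusted p = 0.409), a ribosome hibernation factor, and mtgA (0.79, adjusted p = 0.25), a peptidoglycan glycosyltransferase. The signal of osmC was 597 ± 10.9 (SD, n = 2) in the mutant and 319 ± 68.1 (SD, n = 2) in the wild type. Genes of little-described function or low signal completed the higher group, namely yhdV (0.91), pptA (0.83) and yghJ (0.79). On the lower side, the insertion sequence gene insF4 had a log2 difference of −2.28 (adjusted p = 0.409), from 111 and 24.5 in the mutant against 509 and 125 in the wild type, and its probe set is of shared design. Also on that side were fecR (−1.31), a regulator of ferric citrate uptake, entS (−0.91), an enterobactin exporter, and fhuF (−0.83), a siderophore-iron reductase. So were ygfF (−1.34), fsaA (−0.93), letB (−0.91), hcr (−0.82), and the former gene models b0667 (−0.92) and b0671 (−0.84) near metT. Among them, 6 lay below the 95th percentile of the vector and phage probe sets on all 4 arrays, namely tpr, yjfK, yghJ, ygfF, fecR and fsaA. A further 9 lay below it on both arrays of 1 strain, ygcU, ascF and yhdV in the wild type and insF4, b0667, b0671, entS, letB and hcr in the mutant.

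Single arrays moved several of these differences. The raiA difference was 0.34 without wild-type replicate 1 and 1.26 without wild-type replicate 2, and raiA passed the test without either mutant replicate or wild-type replicate 2 (adjusted p from 2.67e-07 to 0.908 over its alternatives). For ygcU it was 0.97 without wild-type replicate 2 and 2.40 without wild-type replicate 1, and ygcU passed there and without mutant replicate 1 (1.02e-04 to 0.782). For insF4 it was −1.19 without mutant replicate 2 and −3.36 without mutant replicate 1, and insF4 passed in both, without wild-type replicate 2 and with the replicate number as a block (8.21e-17 to 0.787). The osmC gene passed without mutant replicate 1 (0.94) and without wild-type replicate 2 (1.14), in a range of 8.38e-04 to 0.767. Without mutant replicate 1, ascF (1.42), tpr (1.46), ygfF (−1.50) and fhuF (−1.07) passed, and ascF was at 0.41 without mutant replicate 2. The entS gene passed without mutant replicate 2 (−1.45) and was at −0.36 without mutant replicate 1, and mtgA passed without wild-type replicate 2 (0.89). The pptA difference was 0.25 without wild-type replicate 1 and 1.40 without wild-type replicate 2, and that of fsaA −0.42 without mutant replicate 2 and −1.44 without mutant replicate 1. Without mutant replicate 1, fecR was at −0.53 and b0671 at −0.50.

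Apart from luxS, no gene of AI-2 synthesis and the activated methyl cycle, which recycles S-adenosylmethionine, passed the test. Of the 10 tested members, 5 were higher and 5 lower, a count that scaling moved because tam, metH and metK changed sign after median centring and quantile normalization. Only luxS passed, over all genes and adjusted over the list alone. The mtn gene (pfs), whose product makes the substrate of LuxS, measured 1034 ± 304 (SD, n = 2) in the mutant and 968 ± 75.2 (SD, n = 2) in the wild type, a log2 difference of 0.07 (SE 0.18). S-adenosylmethionine synthetase metK (−0.01), the methionine synthases metH (−0.004) and metE (−0.44), the spermidine genes speD (0.01) and speE (0.02), and the methyltransferase genes tam (−0.01), cfa (0.19) and dcm (0.13) did not pass either. The median of the list was 0.00 and its mean −0.56, set by luxS, and camera did not call it (adjusted p = 0.316). Camera called it lower without mutant replicate 1 (adjusted p = 1.36e-06) and without mutant replicate 2 (8.35e-09), and both calls rested on luxS. With luxS left out of the list, an alternative chosen after seeing the data, the adjusted p was 0.868 and 0.716 in these fits and 0.973 with all arrays, in a range of 8.35e-09 to 0.973 over all alternatives of the list. The metE difference was −0.09 without wild-type replicate 1 and −0.79 without wild-type replicate 2. That of cfa was 0.089 without mutant replicate 2 and 0.30 without mutant replicate 1. The exporter gene tqsA was left out as too low, with 17.7 ± 7.60 (SD, n = 2) against 10.2 ± 1.17 (SD, n = 2).

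No tested gene of the lsr operon list, which holds genes of AI-2 uptake and the gene of their repressor LsrR, passed the test. The 3 tested members were lsrR (log2 difference −0.09, 259 ± 15.0 in the mutant and 275 ± 22.6 in the wild type, SD, n = 2), lsrB (−0.10) and lsrC (0.20). The lsrB signals lay below the 95th percentile of the vector and phage probe sets on all 4 arrays, and those of lsrC on 2. The lsrK, lsrA, lsrD, lsrF and lsrG genes were left out as too low, with group means between 7.50 and 74.6. None passed adjusted over the list alone either, and camera gave an adjusted p of 0.999 for the list. Its median was −0.09 and its mean 0.005.

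The genes on either side of luxS did not pass the test either. The adjacent gshA, for glutathione synthesis, had a log2 difference of 0.30 (SE 0.13, adjusted p = 0.662), and csrA, a carbon storage regulator, one of 0.32 (SE 0.14, adjusted p = 0.662). The multidrug efflux genes emrA (−0.29) and emrB (−0.19), their repressor gene mprA (0.03), and yqaA (0.01), yqaB (0.06) and alaS (0.10) completed the list of 8 members. The csrA difference was 0.16 without wild-type replicate 1, and without mutant replicate 2 emrA was at −0.18. Its median was 0.05 and its camera adjusted p 0.636.

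Ribosomal protein genes were higher in the mutant in 49 of 54 cases, with a median log2 difference of 0.21, and camera with its preset correlation called the list higher (adjusted p = 1.78e-09). With an estimated correlation the adjusted p was 0.869. The members named by the fixed rule were rplY (0.60, adjusted p = 0.409), rpmE (0.43), rpsJ (0.39) and rpmG (0.37). No member passed the test over all genes or adjusted over the list alone. Without wild-type replicate 2, rplY (0.81) and rpmE (0.71) passed over all genes, as rplY did with the replicate number as a block. Without wild-type replicate 1 they were at 0.39 and 0.14. Genes of other functions in the brightest 10% had a median of 0.13. After quantile normalization, which removes differences that follow signal level, the median was 0.024, 28 of 54 members were higher, camera turned its direction and the adjusted p was 0.856, in a range of 7.78e-20 to 0.869 over the alternatives. From replicate 1 to 2 these genes rose by a median of 0.16 in the mutant and by 0.19 in the wild type. The preset camera call held in each of the 4 fits that left out an array, where the median ranged from 0.11 without wild-type replicate 1 to 0.33 without wild-type replicate 2.

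Pyrimidine biosynthesis genes were lower in the mutant in 9 of 10 cases with a median of −0.24, and camera called the list lower (adjusted p = 2.90e-04). With an estimated correlation its adjusted p was 0.844. The carbamoyl phosphate synthetase gene carA had a log2 difference of −0.62 (SE 0.17), from 2542 ± 162 (SD, n = 2) in the wild type to 1681 ± 443 (SD, n = 2) in the mutant. The dihydroorotate dehydrogenase gene pyrD (−0.51), the UMP kinase gene pyrH (−0.37) and the aspartate carbamoyltransferase gene pyrB (−0.35) followed. These 4 members passed when adjusted over the list alone, and 0 over all genes (adjusted p = 0.409 for carA). Left-out arrays moved the carA difference from −0.35 without mutant replicate 2 to −0.89 without mutant replicate 1, and carA passed over all genes in the latter and without wild-type replicate 1 (−0.69), with adjusted p from 0.00288 to 0.957 over its alternatives. The pyrD difference was −0.33 without mutant replicate 2. The pyrimidine call was lost without mutant replicate 2 (adjusted p = 0.0687). Over its alternatives the adjusted p of the list ranged from 6.12e-06 to 0.844.

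For arginine, 11 of 15 members were lower with a median of −0.14, and camera called the list lower (adjusted p = 0.0457). With an estimated correlation its adjusted p was 0.869. Besides carA, which is in both lists, the arginine transport genes artP (−0.52, SE 0.16) and artQ (−0.35) and the argininosuccinate synthetase gene argG (−0.44) were named by the rule. Adjusted over the list alone, 2 members passed, carA and artP, and 0 over all genes. The argG difference was −0.03 without mutant replicate 2 and −0.85 without mutant replicate 1. It was −0.27 without wild-type replicate 1, and the artQ difference was −0.19 without mutant replicate 1. Without wild-type replicate 1 artQ was at −0.09 and the list median at −0.09, and without wild-type replicate 2 they were at −0.62 and −0.27. The arginine call was lost without mutant replicate 1 (adjusted p = 0.164), mutant replicate 2 (0.138) or wild-type replicate 1 (0.279). It was also lost after quantile normalization (0.0561), without a filter (0.0967), with the lowest 50% of the probe sets left out (0.135), without an intensity trend (0.0773) and with the vector and phage probe sets kept (0.0546). Over its alternatives adjusted p ranged from 0.0246 to 0.869.

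Oxidative stress genes were higher in 14 of 17 cases, with a median of 0.19, and camera called the list higher (adjusted p = 0.0336). With an estimated correlation its adjusted p was 0.844. The alkyl hydroperoxide reductase gene ahpC (0.40), the DNA-protecting dps (0.37), the redox regulator gene soxR (0.67, below the vector and phage percentile on all arrays) and the efflux gene acrA (0.26) were named by the rule, and none passed over all genes or adjusted over the list alone. Without wild-type replicate 2 ahpC passed over all genes (0.59), and it was at 0.21 without wild-type replicate 1. Without mutant replicate 1 dps was at 0.21 and acrA at 0.15, and dps was at 0.21 without wild-type replicate 1 as well. The list median was 0.10 after quantile normalization. The call was lost without mutant replicate 1 (adjusted p = 0.431) or wild-type replicate 2 (0.0917). It was also lost with the lowest 50% of the probe sets left out (0.0563) and without an intensity trend (0.0528), in a range of 0.00914 to 0.844.

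Genes that depend on RpoS, the sigma factor of stationary phase, were higher in 16 of 25 cases with a median of 0.16 (camera adjusted p = 0.0336). With an estimated correlation the adjusted p was 0.844. Adjusted over the list alone, 1 member passed, osmC, and 0 over all genes. The lipocalin gene blc (0.57), osmE (0.49) and dps, which is also in the oxidative stress list, did not. Without wild-type replicate 1 osmE was at 0.19, and without wild-type replicate 2 at 0.80. The median was 0.037 without a filter and 0.27 with the lowest 50% left out. The call was lost without mutant replicate 1 (adjusted p = 0.101), mutant replicate 2 (0.0896) or wild-type replicate 1 (0.220). It was also lost without a filter (0.283), with the lowest 50% left out (0.0551), without an intensity trend (0.0528) and with the vector and phage probe sets kept (0.0829). The range over its alternatives was 0.0168 to 0.844.

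Chemotaxis genes were higher in 11 of 11 cases with a median of 0.14 (camera adjusted p = 0.0336). With an estimated correlation the adjusted p was 0.844. The aspartate receptor gene tar was at 0.28, from 7602 ± 67.6 (SD, n = 2) in the wild type to 9243 ± 254 (SD, n = 2) in the mutant. The signalling genes cheW (0.24) and cheA (0.22) and the aerotaxis receptor gene aer (0.20) followed, and no member passed over all genes or adjusted over the list alone. Without wild-type replicate 1 cheW was at 0.10 and cheA at 0.13, without wild-type replicate 2 cheW was at 0.38, and without mutant replicate 2 cheA was at 0.12. The median was 0.085 after quantile normalization and 0.22 without wild-type replicate 2. The call was lost without mutant replicate 1 (adjusted p = 0.180), mutant replicate 2 (0.171) or wild-type replicate 1 (0.220). It was also lost after quantile normalization (0.341), with the lowest 50% left out (0.0563) and without an intensity trend (0.0784). The range over its alternatives was 0.00557 to 0.844.

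Camera called 6 of the 32 lists in all, 4 higher and 2 lower, and 0 with an estimated correlation (lowest unadjusted p = 0.0898, lowest adjusted p = 0.844). For oxidative stress, chemotaxis and RpoS the estimated correlation, 0.0055, −0.0083 and −0.025, lay below the preset 0.01. Their unadjusted camera p still rose, from 0.00347 to 0.0944, from 0.00426 to 0.0955 and from 0.00525 to 0.0898. Correlated members therefore do not account for these lost calls. The estimated test rests on the few residual degrees of freedom of 4 arrays, and its 0 calls cannot decide whether a list differs. The directional test of fry called 0 lists as well (lowest adjusted p = 0.506). The remaining 26 lists, fixed before the data were examined, were not called, and apart from luxS no member of them passed over all genes. Adjusted over the list alone, 2 members of these passed, luxS and ilvM. Some of their named members passed over all genes when an array was left out. Without wild-type replicate 2 these were ilvM (0.83), cspE (0.65), yebG (0.69), fliO (−0.60) and sdhC (−0.58), and without mutant replicate 1 mmuM (−1.86) and fhuF (−1.07). By contrast, cspE was at 0.019, yebG at 0.14 and sdhC at −0.28 without wild-type replicate 1, and without mutant replicate 2 mmuM was at 0.075.

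**Figure D3:**
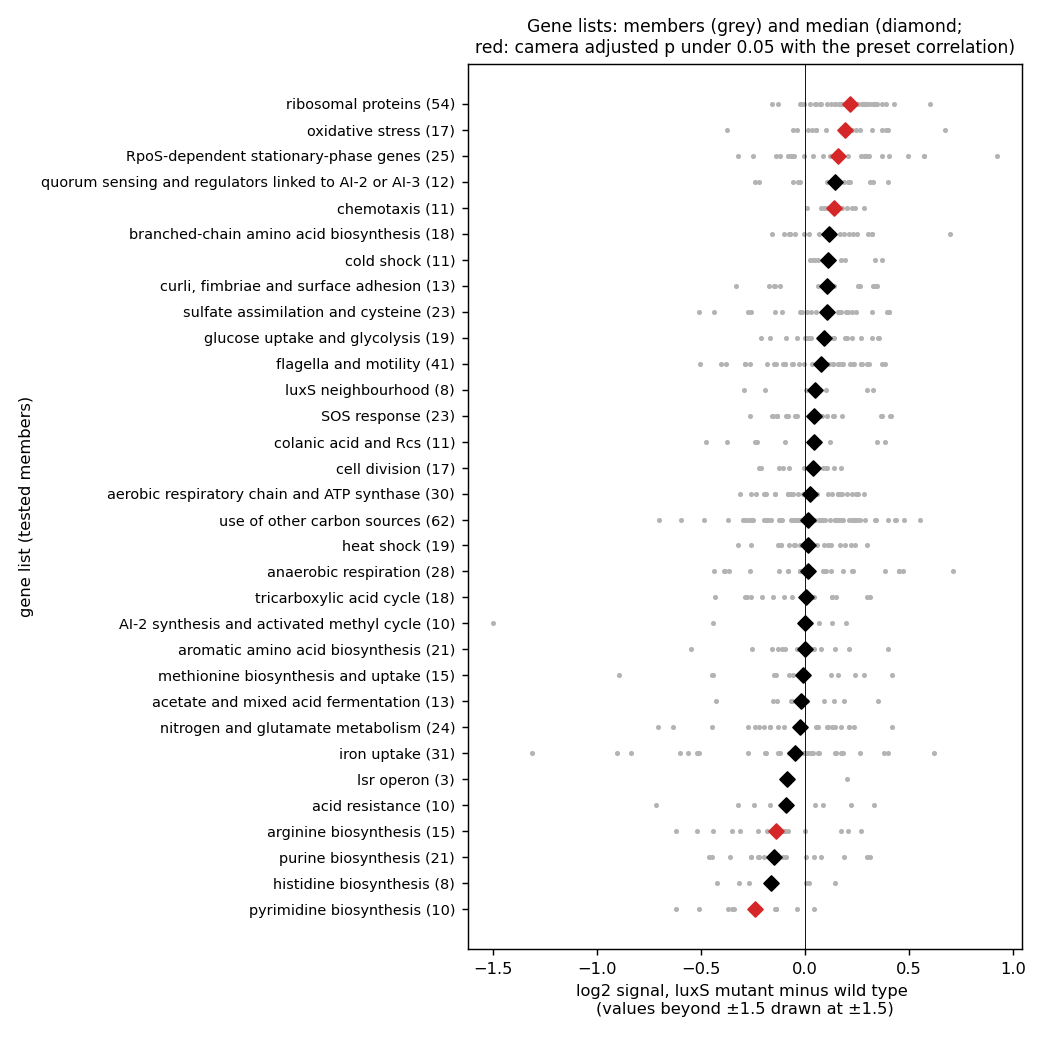
Each grey point is the log2 difference, luxS mutant minus wild type, of 1 tested member of a gene list, with values beyond 1.5 in either direction drawn at 1.5, and each diamond is the median of a list. Red diamonds mark the 6 lists called by camera with its preset correlation, from the ribosomal proteins (median 0.21) to pyrimidine biosynthesis (median −0.24).

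Among amino acid and nucleotide pathways, purine biosynthesis had a median of −0.15 over 21 members (camera adjusted p = 0.105), with codB at −0.45 and gcvH at 0.30. Histidine biosynthesis had a median of −0.17 over 8 members (adjusted p = 0.157), with hisH at −0.32 and hisF at −0.27. Both were called lower without wild-type replicate 2, with adjusted p of 0.0251 and 0.0241, in ranges of 0.0251 to 0.703 and 0.0241 to 0.882 over their alternatives. Branched-chain amino acid biosynthesis had a median of 0.12 over 18 members (adjusted p = 0.175), with ilvM, a subunit of acetolactate synthase, at 0.70 and leuC at 0.30. It was called higher without wild-type replicate 1 (adjusted p = 0.0282, in a range of 0.0282 to 0.915). Aromatic amino acid biosynthesis had a median of 0.00 over 21 members (adjusted p = 0.875), with pheA at 0.40 and the tyrosine transporter gene tyrP at −0.55. Methionine biosynthesis and uptake had a median of −0.01 over 15 members (adjusted p = 0.767), with metE at −0.44 and mmuM at −0.89. Sulfate assimilation and cysteine had a median of 0.10 over 23 members (adjusted p = 0.693), with cysE at −0.26 and cysK at 0.24. Nitrogen and glutamate metabolism had a median of −0.03 over 24 members (adjusted p = 0.636), with astC at −0.71 and argT at −0.45. Both mutant signals of astC and of tyrP lay below the vector and phage percentile. Single arrays moved several of these members by over 1.5 times. Without mutant replicate 2 astC was at −0.34, argT at −0.21, codB at −0.22 and cysE at −0.16, and without mutant replicate 1 astC was at −1.07, argT at −0.68 and codB at −0.67. Without wild-type replicate 1 codB was at −0.27, metE at −0.09, tyrP at −0.31, hisH at −0.19, gcvH at 0.20 and cysK at 0.11. Without wild-type replicate 2 metE was at −0.79, cysK at 0.38 and leuC at 0.18.

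In central metabolism, glucose uptake and glycolysis had a median of 0.09 over 19 members (camera adjusted p = 0.123), with the phosphotransferase genes crr at 0.35 and ptsI at 0.32. The tricarboxylic acid cycle had a median of 0.01 and a mean of −0.04 over 18 members, with a test direction of lower (adjusted p = 0.636), sdhC at −0.43 and icd at 0.31. Acetate and mixed acid fermentation had a median of −0.02 over 13 members (adjusted p = 0.999), with the lactate dehydrogenase gene ldhA at 0.35 and frdD at −0.43. The use of other carbon sources had a median of 0.01 over 62 members (adjusted p = 0.846), with the maltose activator gene malT at 0.55 and rbsD at 0.40. The aerobic respiratory chain and ATP synthase had a median of 0.02 over 30 members (adjusted p = 0.785), with nuoK at −0.31 and ndh at 0.28. Anaerobic respiration had a median of 0.01 over 28 members (adjusted p = 0.693), with hycG at 0.71 and narX at 0.38. Iron uptake had a median of −0.05 over 31 members, 14 higher and 17 lower (adjusted p = 0.178), with fhuF and fecR as its leading members. The crr difference was 0.15 without wild-type replicate 1 and 0.56 without wild-type replicate 2, that of icd 0.20 without mutant replicate 2, and that of rbsD 0.22 without mutant replicate 1.

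Among regulators and surface structures, the list of quorum sensing and regulators linked to AI-2 or the signal AI-3 had a median of 0.15 over 12 members (camera adjusted p = 0.208). The RNA chaperone gene hfq was at 0.31 and csrA at 0.32 in it, and it was called higher without wild-type replicate 2 (adjusted p = 0.0241, in a range of 0.0241 to 0.955). Flagella and motility had a median of 0.08 over 41 members (adjusted p = 0.546), with fliO at −0.51 and fliL at −0.40, opposite in sign to the median. Curli, fimbriae and surface adhesion had a median of 0.11 over 13 members (adjusted p = 0.587), with the fimbrial subunit gene fimA at 0.26 and flu at 0.34. Colanic acid and Rcs had a median of 0.04, a mean of −0.04 and a test direction of lower over 11 members (adjusted p = 0.767), with wcaJ at 0.38, below the vector and phage percentile on all arrays, and ugd at −0.37. Cell division had a median of 0.04 over 17 members (adjusted p = 0.890), with minD at 0.17 and the LuxR-type regulator gene sdiA at −0.22. The flu difference was 0.14 without mutant replicate 1 or wild-type replicate 2 and 0.54 without either other array. For csrA it was 0.16 without wild-type replicate 1, without mutant replicate 2 ugd was at −0.20, and sdiA was at −0.12 without mutant replicate 1 and −0.13 without wild-type replicate 2.

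Among the other stress responses, cold shock genes had a median of 0.11 over 11 members (camera adjusted p = 0.0975), with cspC at 0.37 and cspE at 0.33. The cold shock list was called higher without wild-type replicate 2 (adjusted p = 0.0208, in a range of 0.0208 to 0.816). Heat shock genes had a median of 0.01 over 19 members (adjusted p = 0.767), with hslV at 0.30 and groS at 0.24. The SOS response to DNA damage had a median of 0.04 over 23 members (adjusted p = 0.476), with yebG at 0.41 and ssb at 0.37. Acid resistance had a median of −0.09 over 10 members (adjusted p = 0.693), with the arginine decarboxylase gene adiA at −0.72 and its regulator gene adiY at 0.33. Differences without wild-type replicate 1 were 0.24 for cspC, 0.019 for cspE, 0.14 for yebG and 0.19 for ssb, and without mutant replicate 2 adiA was at −0.42. Both mutant signals of adiA lay below the vector and phage percentile.

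In the stretches between genes, 0 of 2164 tested probe sets differed with limma at an adjusted p under 0.05 (lowest adjusted p = 0.0889). At an unadjusted p under 0.05, 129 did, 12 higher and 117 lower, where 108 would be expected by chance. After quantile normalization 25 were higher and 77 lower. The median log2 difference was −0.16 and after quantile normalization −0.06. Intergenic probe sets at the signal levels of the tested genes (1272) had a median of −0.12, against −0.003 for genes at those levels. The median signal of all intergenic probe sets was 52.3 and 57.3 on mutant replicates 1 and 2. On wild-type replicates 1 and 2 it was 68.0 and 58.6. Wild-type replicate 2 lay closer to mutant replicate 2 than to wild-type replicate 1, so spread between arrays cannot be told apart from the strain. The lowest adjusted p belonged to IG_2029, a probe set at 3253548 to 3253728 on the reverse strand in the numbering of its name, with the genome build not given, which the platform annotation assigns to yhaM (cyuA). It was singled out after its values were seen, and measured 667 ± 59.4 (SD, n = 2) in the mutant against 192 ± 74.0 (SD, n = 2) in the wild type, a log2 difference of 1.85. Leaving out 1 array gave 32 called intergenic probe sets for mutant replicate 1 and 23 for mutant replicate 2. It gave 1 for wild-type replicate 1 and 0 for wild-type replicate 2.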

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

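The fits with all probe sets kept, shared designs left out, vector and phage probe sets kept, rRNA and tRNA genes left out, or luxS left out of its list were chosen after seeing the data, and the other alternatives before. The luxS difference kept its sign throughout, from −4.38 to −6.75 when an array was left out, values of measured signals that give no size, since the mutant signals were not above those of vector and phage probe sets. It was −5.57 with an adjusted p of 0.201 without an intensity trend and −5.57 with 0.572 under a robust trend, since both change only the shared variance. The count of 3 genes became 1 without a filter, 0 without a trend and 0 with a robust trend, and ranged from 8 to 56 when an array was left out. It was 4 with all probe sets kept, 2 without shared designs, 3 with vector and phage probe sets and 2 without rRNA and tRNA genes. The count of 7 genes at least 2-fold apart without overlap became 4 with an offset, 123 without a filter and 2 with the lowest 50% left out. It ranged from 12 to 36 when an array was left out, where chance leaves 66.7% of genes without overlap, so those counts are not comparable. The count of 0 intergenic probe sets became 1 with the lowest 50% left out and ranged from 0 to 32 when an array was left out. The count of 6 lists became 3 after quantile normalization, 2 with the lowest 50% left out, 2 without a trend, 0 with an estimated correlation and 0 with fry, and was 3 to 9 when an array was left out. With vector and phage probe sets kept it was 4. Low signals, near those of the vector and phage probe sets, limit the genes left out by the filter. Apart from these filters and variance models, the cause was not tested.

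Some differences of genes that did not pass the test changed sign. After median centring tam was at 0.015, metH at 0.016 and metK at 0.0099. After quantile normalization tam was at 0.047, metH at 0.042, metK at 0.032, lsrB at 0.0062 and alaS at −0.013, and the ribosomal protein list had a median of 0.024 with its test direction turned. When an array was left out, the differences that changed sign ranged from −0.062 to 0.051 for tam, −0.11 to 0.086 for metK, −0.24 to 0.37 for mtn, −0.12 to 0.13 for speD, −0.084 to 0.12 for speE, −0.48 to 0.28 for lsrB, −0.12 to 0.13 for yqaA, −0.22 to 0.28 for mprA, −0.017 to 0.15 for yqaB, −0.096 to 0.088 for metH, −0.70 to 0.31 for emrB and −1.86 to 0.075 for mmuM. The cause was not tested. Among the single-gene values over all alternatives, luxS included, 1596 kept their direction and their side of the threshold, 9 lost a call (luxS in 2, cyuA in 3 and metT in 4), 29 gained one and 27 changed sign.

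The replicate numbers were also fitted as a replicate block. It called 16 genes, 13 higher and 3 lower, with the 3 genes of the main comparison among them and 10 rRNA genes, 34 intergenic probe sets and 5 lists. Of the lists, 4 were among the 6, arginine (adjusted p = 0.0574) and RpoS (0.0769) were not called, and glucose uptake and glycolysis was (0.0279). The differences of replicate 1 minus 2 in the strains correlated across genes at 0.029 (Pearson) and 0.066 (Spearman), genes not being independent replicates, so the numbers were not taken to pair the arrays. The medians of the ribosomal protein and rRNA genes did rise from replicate 1 to 2 in both strains.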

Other observations

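The RNA classes and the explanations by a single faulty probe set, a gain of the region and the recovery of short RNA were tested only after the results were seen. The 18 rRNA probe sets, all of shared design, were higher in the mutant with a median log2 difference of 0.43, 15 of them without overlap (camera p = 0.156 with an estimated correlation). After quantile normalization their median was 0.17 and 17 of 18 were higher. From replicate 1 to 2 they rose by a median of 0.30 in the mutant and by 0.27 in the wild type, and none passed limma over all genes. Of the 73 tested tRNA genes 35 were higher and 38 lower, and 1 passed, metT. The 4 tested tRNA genes between csrA and yqaB, near luxS, were all lower without overlap, namely argQ (−0.51), argV (−0.49), argZ (−0.45) and serV (−0.27). The probe sets of argQ, argV and argZ are of shared design, so their signals can include each other's transcripts. The 4 genes had a median of −0.47 (camera p = 0.0649 with an estimated correlation). The initiator methionine tRNA genes had a median of 0.13 over 4 probe sets.

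The ribosomal protein genes had a median of 0.21 higher in the mutant. Random lists of other genes matched on signal level had a median of 0.22 (95% of them from 0.18 to 0.27), and 6117 of 10000 reached the ribosomal median. After quantile normalization the ribosomal median was 0.024, against 0.034 for matched lists, so a stretch of bright signals between arrays may account for the shift, and a rise of highly expressed genes as a group would look alike. From replicate 1 to 2 the same genes rose by a median of 0.19 in the wild type and 0.16 in the mutant. With 2 arrays each, the spread between arrays of one strain cannot be told apart from the strain. An effect of the luxS mutation stays open.

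The cyuA and cyuP probe sets were higher in the mutant by 0.98 to 1.52. For the call of cyuA, a single faulty probe set was argued against by the other probe set of that gene (b3109), which the gene test did not use and which was higher by 1.52 (SE 0.18) without overlap. Cross-hybridisation was not tested. A gain reaching into the neighbouring genes was argued against by their 7 gene probe sets kept by the filter. Their median was −0.14 (95% bootstrap interval −0.20 to 0.10). The interval resamples probe sets of the same arrays, so it leaves out the spread between arrays. Of these neighbours, yhaK lay below the vector and phage 95th percentile on every array. The yhaJ, yhaL and tdcE signals lay above it on every array and were at −0.20, 0.10 and −0.002. Intergenic probe sets were not among the 7. Of these, IG_2030 was higher by 1.46 (SE 0.29) without overlap, and IG_2031 was at 0.13. Where IG_2030 lies against cyuA and cyuP was not established, so how far the rise reaches between genes stays open. A gain of cyuA and cyuP alone was not tested. An effect of the luxS mutation and a difference between cultures unrelated to luxS both stay open and were not tested.

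The metT region (b0664 to b0673) had 9 probe sets, all lower in the mutant, 8 of them without overlap. After median centring 5 of its 6 tested tRNA genes were lower, and after quantile normalization 6. Lower recovery of short RNA in the mutant preparations was argued against by the 67 tRNA genes outside the region, argQ, argV, argZ and serV included, whose median was 0.0049 (95% bootstrap interval −0.04 to 0.079) against −0.37 for the 6 tRNA genes of the region. This interval resamples genes measured on the same arrays and leaves out the spread between arrays. From replicate 1 to 2 all 73 tested tRNA genes rose by a median of 0.11 in the mutant and 0.24 in the wild type. The 6 tRNA genes of the region rose by 0.05 and 0.22. That one tRNA species was read by several probe sets cannot be told apart from a fall of the region, since 3 of the 4 probe sets of unshared design were lower without overlap (b0667, b0669 and b0671) and leuW was at −0.01. On both mutant arrays those 3 lay below the 95th percentile of the vector and phage probe sets, so the size of their fall is uncertain. On the wild-type arrays, where it was 157 and 119, b0667 (203 and 135) and b0669 (168 and 147) lay above it. The b0671 signal lay above it only on wild-type replicate 2. A lower level of the tRNA species read by the metT and metU probe sets in the luxS mutant may be followed up as a hypothesis.

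The split by strain called 3 genes and each of the other splits called 0. The 4 arrays have too few splits (3) for a share under 0.05, so this comparison cannot decide. Of the called genes, luxS is the mutated gene, so its call in the split by strain was set by the design. The 81 vector, phage and spike probe sets gave 0 calls with limma (lowest adjusted p = 0.783, 2 at an unadjusted p under 0.05).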
